A study of Arabidopsis thaliana with 4 samples.

How the data were processed

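Gene expression was measured in seedlings of Arabidopsis thaliana ecotype Col-0, the standard laboratory line, that had been kept with or without the volatiles of Pseudomonas syringae DC3000, a bacterium that causes leaf spot disease in tomato and Arabidopsis. Per the labels' protocols, plants grew in the upper part of upright square plates and the bacteria in the lower part, so that the air space was shared, and control plates held no bacteria. The series design gives 8 days of growth and 12 hours of exposure. The sample labels give 12 days, and the difference is not resolved in the sources used here. Each of the 4 samples is 1 two-colour Agilent array with control RNA in the green dye Cy3 and exposed RNA in the red dye Cy5, per the labels. No array had the dyes swapped, so a preference of a transcript for 1 dye cannot be separated from an effect of exposure. Per the labels' protocols, total RNA was extracted with Trizol and reverse transcribed from a T-rich primer with a Cy-labelled nucleotide, while the series design speaks of labelled cRNA. Nothing in the labels says that the 4 exposed or the 4 control RNAs came from separate batches of plants. The p-values therefore measure the spread between these 4 arrays, which may be technical.

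The deposited scanner files hold spot intensity on a linear scale for 45220 spots per array, of which 43803 are gene spots, with the local background and the quality marks of each spot, per the file headers. They were made with Agilent Feature Extraction, for which the file headers give version 11.5.1.1 and the submitters' processing notes give 8.5.1.1. The software's own log ratio, a deposited log10 value of Cy5 over Cy3 after background and dye correction per the file headers, was used as an alternative after conversion to log2. The series matrix holds values that the labels call log2 of exposed over control. Set against the scanner columns with a tolerance of 0.001, the deposited log2 column of array 1 equalled log2 of processed Cy5 over processed Cy3 signal at all 45220 spots. The columns of arrays 2, 3 and 4 instead equalled log2 of the Cy3 signal error over the processed Cy5 signal at 45219, 45220 and 45220 spots. Their medians were -3.17, -3.17 and -3.19 against -0.042 for array 1, and the correlation across spots with the scanner's log ratio was -0.202, -0.214 and -0.486 against 0.876. No centring or direction other than these formulas was found, and the matrix was not used for any comparison.

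All values were computed in R 4.3.3 with limma 3.58.1. The planned mean spot signal is not a column of these files, so the median signal was used with the median local background. The background was corrected with normexp (offset 50), and log ratios were normalized within each array by loess with control spots and outlier spots at weight 0. Outlier spots numbered 19, 19, 13 and 142 on arrays 1 to 4 and were left out, no gene spot was saturated, and 50 probes spotted several times were averaged. A positive log2 ratio means more signal in exposed plants. Of 43603 probes, 38413 carry a locus identifier, standing for 29030 loci, and 5190 carry none and were left out of the gene comparison. A probe was tested when it was well above background in the same channel on at least 3 of the 4 arrays, which left 31106 probes of 22690 genes. Array 4 had 97.2% of gene spots well above background in Cy3 and 99.6% in Cy5. The filter therefore rested mostly on arrays 1 to 3. A gene was represented by its brightest tested probe. Of the tested genes 6495 had several tested probes, and the second probe had the same sign in 218 of the 269 called genes that had one. Names come from an NCBI gene table of the TAIR10.1 assembly, which held 22447 of the tested loci and not 243 others, and 9476 genes had a symbol other than the locus. The file headers give another annotation, so no coordinates are printed.

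Arrays were fitted with lmFit and eBayes on the log2 ratio against 0, with Benjamini-Hochberg adjustment over all tested genes, two-sided, and a threshold of 0.05. Tested on simulated data with 200 changed genes in 22690, the 4-array fit recovered 25% of genes changed by 0.5 and 85% of genes changed by 1 on the log2 scale and called 0 unchanged genes. A fit of 3 arrays with the spread of arrays 1 to 3 recovered 50% and 97% and called 1 unchanged gene. The simulated genes and arrays were independent, without dye preference, and array 4 had the same spread at every brightness. These figures therefore do not give the error rate of the real calls. The 28 gene lists, 436 of whose 448 members were tested, were compared with all other genes by camera with a preset inter-gene correlation of 0.01 and then with an estimated correlation. They were also tested by fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Gene families were found by words in the symbols and synonyms of the gene table and tested in the same way when at least 10 genes were tested. This left 21 families, and defensins, with 7 tested genes, were left out. The word AP2 was restricted to whole words after its matches, and the first test results, were seen. The wider match held 158 genes and was not called (adjusted p = 0.249), while the restricted match holds 37 genes and was called (adjusted p = 0.0178).

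The genes named are the 12 largest rises and the 12 largest falls among genes with adjusted p below 0.05 and the same sign on every array with a value, at least 3, up to 3 members of each list with the lowest p, and the reference genes ACT2, UBQ10, PP2AA3 and TIP41. Genes named outside this rule are named as called members of a list or family, or are chloroplast-encoded loci chosen after their values were seen. The tests, lists, rule and alternatives were fixed before the data were examined, except where a later choice is said. Where a gene was not well above background in 1 channel on every array, its change is given as a bound, the mean of the brighter channel against the mean of, per array, the higher of the lowest signal well above background and the gene's own signal, from channel values after loess and Aquantile normalization. The alternatives were other background corrections and normalizations, other filters on dim probes, outlier spots kept, channels taken as separate samples, slide as a random block, another variance model, array weights, the mean of a gene's probes and leaving out each array. Counting arrays 1 to 3 as 1 sample, list tests with an estimated correlation without array 4 and families without each array were added after the data were seen, and the narrower AP2 match replaced the wider one, which was run first, after the results of the wider one were seen. Slides each held 2 arrays, arrays 1 and 2 on one and arrays 3 and 4 on the other. The number of arrays, 4, limits the precision, and 75.1% to 99.6% of gene spots were well above background.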

Results

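Transcript levels were compared between Arabidopsis seedlings that shared the air space of a plate with Pseudomonas syringae DC3000 and seedlings on plates without bacteria. The exposure lasted 12 hours per the series design. The 4 samples were 4 two-colour arrays in 1 group, each holding control RNA and exposed RNA side by side, so that every log2 ratio is exposed over control. The question the design addresses is which transcripts respond to microbial volatile compounds without contact with the microbe. On arrays 1 to 3 the median gene spot read 292 to 362.5 scanner units in the control channel and 336 to 373 in the exposed channel, and 75.1% to 75.4% and 77.7% to 78.9% of gene spots were well above background. On array 4 these values were 575.5 and 1286 units and 97.2% and 99.6%. Across genes, which are not independent replicates, the log2 ratios of arrays 1 to 3 correlated with r = 0.648 to 0.779, and those of array 4 correlated with the other arrays with r = 0.221 to 0.288. On 23 probes spotted 5 times, arrays 1 to 3 differed by about as much as the noise between spots. The mean of the 5 spots varied between these arrays by a median SD of 0.0497, where the spread of spots within an array gives 0.0532. A median of SDs over 3 arrays tends to lie below the true SD. A small difference beyond spot noise is therefore not excluded. The 4 arrays were kept as 4 samples, as the labels number them, although the p-values may then measure only technical spread. Every gene call below rests on this choice, since counting arrays 1 to 3 as 1 sample left 0 called genes.

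**Figure D1:**
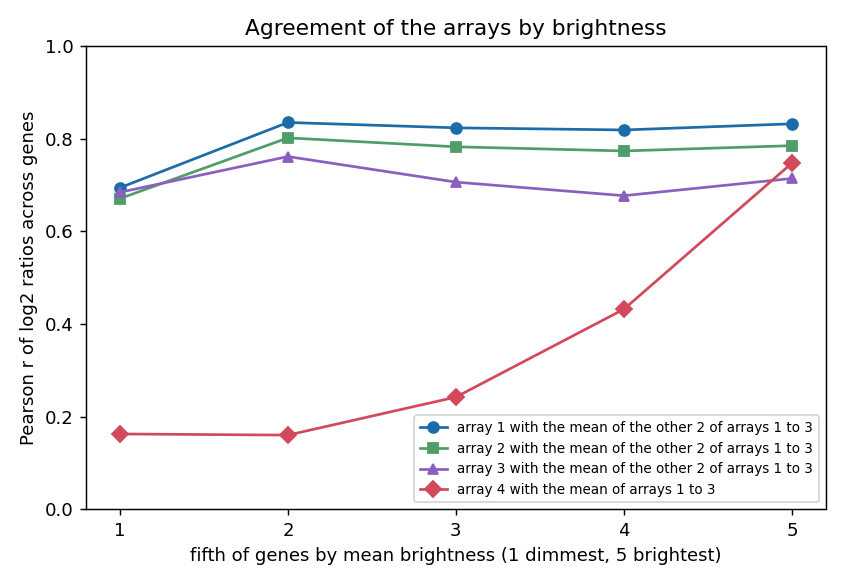
Pearson r of the log2 ratios across genes (vertical axis) in 5 equal bins of the tested genes by mean brightness (horizontal axis), for array 4 against the mean of arrays 1 to 3 and for each of arrays 1 to 3 against the mean of the other 2. Array 4 correlated at 0.162 in the dimmest bin and 0.747 in the brightest, while arrays 1 to 3 lay between 0.671 and 0.835 in every bin.

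The largest rise in exposed plants was in AT5G04120, which has no symbol in the gene table, at 2.36-fold (log2 ratio 1.24 ± 0.091 SE, n = 4). The protease gene AT5G10760, also called AED1 (apoplastic, EDS1-dependent), rose 2.14-fold, and the beta-1,3-glucanase gene BGL2, better known as the defence marker PR2, rose 1.85-fold. The largest fitted falls were in the glutathione transferase gene GSTU3 at 3.38-fold (log2 ratio -1.76 ± 0.163 SE, n = 4) and in ABCG40, which encodes a plasma membrane importer of abscisic acid, at 3.36-fold. In the exposed channel GSTU3 was well above background on 3 of the 4 arrays, so that the size of its fall is less certain. PR1, the most used marker of salicylic acid responses, fell 2.68-fold (log2 ratio -1.42 ± 0.062 SE, n = 4) and had the lowest adjusted p among these genes, 0.0038.

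Among 22690 tested genes, 772 had an adjusted p below 0.05 in limma, 358 higher and 414 lower in exposed plants, or 46.4% higher. The median change of these genes was 1.35-fold, and 14 had a fitted change of at least 2-fold, 6 up and 8 down. One of the 6, AT3G43572, has only a bound below 2-fold, given with its values. The other large rises were PCR1, a gene of the plant cadmium resistance family (2.13-fold, adjusted p = 0.047), AT1G07590 (log2 ratio 1.07), AT1G21525 (2.01-fold), AT4G11210 (1.96-fold), AT5G26690 (1.92-fold), the transcription factor genes WRKY50 (1.90-fold) and ZAT7 (1.88-fold), and AT3G48640 (1.88-fold). AT1G07590 was read by a second, dimmer probe that gave a log2 ratio of -0.27. AT3G43572 was not well above background in the control channel on any array and was at least 1.87-fold higher in exposed plants, a bound taken from channel values after loess and Aquantile normalization that is open to dye bias, with an adjusted p of 0.013 in limma. The other large falls were DXPS1, annotated as a deoxyxylulose phosphate synthase of plastid isoprenoid synthesis (3.04-fold), the lipid transfer protein gene LTP4 (2.83-fold), the membrane protein gene DMP1 (2.34-fold), the nudix hydrolase gene NUDT24 (2.23-fold) and the xyloglucan endotransglucosylase gene XTH10 (2.09-fold). TPS04, the geranyllinalool synthase that starts the synthesis of a volatile homoterpene, fell 1.83-fold, the mitochondrial alternative oxidase gene AOX1D 1.82-fold, the dehydration-responsive gene LTI78 (RD29A) 1.82-fold and the caleosin gene RD20 1.79-fold. A second probe of LTI78 gave 0.045 against -0.86. By the rule that chose them, these 24 genes had the same sign on all 4 arrays and an adjusted p below 0.05. Their adjusted p lay between 0.0038 and 0.047.

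The number of called genes depended on single arrays. Without array 4 the count was 7067 (3834 higher, 3233 lower), with 771 of the 772 genes among them in the same direction, while without array 1, array 2 or array 3 limma called 0 genes, with 3528, 3863 and 3451 at an unadjusted p below 0.05. With arrays 1 to 3 counted as 1 sample beside array 4, a choice made after the data were seen, 0 genes were called and 1317 had an unadjusted p below 0.05. The 2-fold count was 16 without array 4 and 0 in each of these other fits, and its direction depended on the scaling, with 104 up and 10 down by the scanner software's log ratio, 33 up and 9 down with plain background subtraction and 12 up and 7 down with median centring. Median centring in place of loess called 216 genes, 166 higher and 50 lower, and plain background subtraction called 656 higher and 489 lower. With the mean of each gene's probes LTI78 (-0.41, adjusted p = 0.084), PAD4 (0.31, 0.0811), RBCS1A (0.25, 0.0872), BAM5 (0.091, 0.344), LNK2 (-0.067, 0.726) and PYK10 (0.26, 0.0621) moved by over 1.5 times and were not called.

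**Figure D2:**
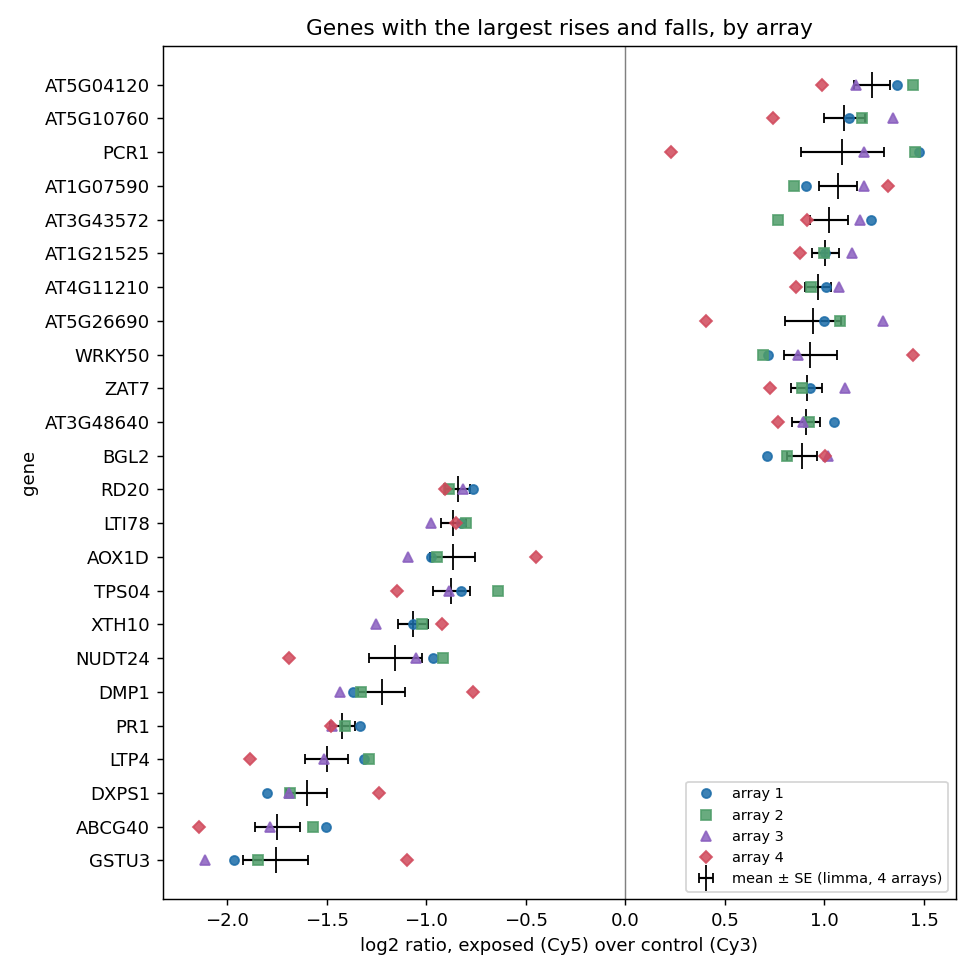
Log2 ratio of exposed over control (horizontal axis) on each of the 4 arrays (symbols) for the 12 genes with the largest rises and the 12 with the largest falls, with the mean and its SE from limma in black; AT3G43572 is drawn at its measured value although its control signal was not well above background. PR1 lies between -1.48 and -1.33 on every array, while array 4 lies apart from the others for PCR1 (0.23 against 1.48 on array 1), DMP1 (-0.77 against -1.43 to -1.33) and GSTU3 (-1.10 against -2.11 to -1.85).

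Of 20 tested genes of salicylic acid synthesis and response, 5 rose, 2 fell and 13 were not called, and 9 were up and 2 down when adjusted over the list alone. Besides PR2, the regulators PAD4 (1.51-fold) and SARD1, a transcription factor that drives salicylic acid synthesis, rose (log2 ratio 0.62), as did PR5 (0.47) and the transporter gene EDS5 (0.36, with a second probe at -0.037). PR1 and FMO1, whose product makes the systemic resistance signal N-hydroxypipecolic acid, fell (-1.42 and -0.76), opposite to the rest of the called members. The list had a median log2 ratio of 0.22 and shifted up against other genes (camera adjusted p = 0.0024 over 28 lists), with an adjusted p of 0.502 with an estimated correlation. Its medians were 0.31, 0.26 and 0.30 on arrays 1 to 3 and 0.010 on array 4, the array that stood apart.

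No member of the pattern recognition and early immune list was called among 19, over all genes or adjusted over the list alone. Its lowest p belonged to PHI-1 (log2 ratio 0.41, adjusted p = 0.0746), WRKY29 (0.28) and the receptor kinase gene FRK1 (0.17). The list median was 0.11 (adjusted p = 0.0806), at 0.15 to 0.18 on arrays 1 to 3 and -0.17 on array 4, and without array 4 the list was called (median 0.17, adjusted p = 0.0051, with 0.00436 to 0.588 over all camera settings tried), but with an estimated correlation no list was called without array 4 (lowest adjusted p = 0.534). Of 22 jasmonate genes, the aminotransferase gene TAT3 rose (0.60), while the storage protein gene VSP2 (-0.43) and the synthesis gene AOC2 (-0.31) fell. Adjusted over the list alone these counts were 1 up and 5 down, and the list was not called (median -0.12, adjusted p = 0.123), with a median of -0.031 without array 4. Of 19 ethylene genes, the chitinase gene PR3 rose (0.43) and the defensin genes PDF1.3 (-0.45) and PDF1.2C (-0.46, adjusted p = 0.04996) fell, with the same counts of 1 up and 2 down over the list alone. A second probe of PR3 gave 0.17. The ethylene list was not called (adjusted p = 0.65), and its median of 0.017 and its mean of -0.036 differed in sign.

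Of 22 tested dehydration and abscisic acid genes, 4 fell, none rose and 18 were not called, and 8 were down and 1 up when adjusted over the list alone. The cold- and dehydration-induced genes COR15B (1.68-fold), COR15A (1.56-fold) and ERD10 (log2 ratio -0.32) fell with RD29A. The list shifted down against other genes, with a median of -0.11 and array medians between -0.30 and -0.13 (camera adjusted p = 6.2e-04), and with an adjusted p of 0.467 with an estimated correlation. The median was -0.17 without array 4 and -0.26 by the scanner software's log ratio.

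Of 16 sulfur assimilation and starvation genes, 3 fell, none rose and 13 were not called, and 6 were down over the list alone. Those called were SHM7 (1.46-fold), SDI1, a sulfur starvation marker that represses glucosinolate synthesis (1.32-fold), and the glutathione-degrading enzyme gene GGCT2.1 (1.32-fold). A second probe of SHM7 gave a log2 ratio of -0.23 against -0.54. The list shifted down, with a median of -0.13 (adjusted p = 0.0076), and with an adjusted p of 0.483 with an estimated correlation. The median was -0.050 with median centring. Aliphatic glucosinolate genes had 0 of 12 called over all genes or over the list alone, led by CYP79F1 (-0.34), MAM1 (-0.24) and MYB29 (-0.30). As a group they shifted down (median -0.15, adjusted p = 0.025), with an adjusted p of 0.502 with an estimated correlation and 0.1002 without array 3 (0.00592 to 0.502 over all camera settings tried). A second probe of CYP79F1 gave -0.063 against -0.34. Of 12 indole glucosinolate and camalexin genes 0 were called over all genes or over the list alone. The camalexin genes PAD3 and CYP71A13 were at -0.61 to -0.74 on arrays 1 to 3 and at 0.21 and 0.40 on array 4. GGP1 was at -0.15, and the list was not called (median -0.045, adjusted p = 0.531). Of 7 genes of plant volatile synthesis, TPS04 fell. The others with low p, CYP82G1 (-0.26) and HPL1 (-0.20), were not called, and 1 down was the count over the list alone. This list had a median of -0.17 (adjusted p = 0.103). It was -0.027 with no filter on dim probes and -0.30 by the scanner software's log ratio. The list was called without array 4 (median -0.17, adjusted p = 0.0174, with 0.00346 to 0.483 over all camera settings tried), a call lost there with an estimated correlation (adjusted p of at least 0.534).

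Of 17 circadian clock genes, 2 fell, none rose and 15 were not called, and 6 were down over the list alone. The clock genes PRR3 (-0.37) and LNK2 (-0.35, with a second probe at 0.22) fell, while TOC1 (-0.37, adjusted p = 0.0535) missed the threshold. The list shifted down, with a median of -0.14 (adjusted p = 0.0209), with an adjusted p of 0.467 with an estimated correlation, 0.0612 without array 2 and 0.0619 without array 3 (0.00112 to 0.467 over all camera settings tried).

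Of 11 growth-related cell wall genes, 2 rose, none fell and 9 were not called, and 5 were up over the list alone. The called members were the xyloglucan endotransglucosylase genes XTH22 (log2 ratio 0.38) and XTH18 (1.26-fold), and XTH15 was at 0.32 (adjusted p = 0.0613). The list shifted up, with a median of 0.12 and array medians between 0.16 and 0.27 (adjusted p = 0.0024), and with an adjusted p of 0.467 with an estimated correlation. The median was 0.19 without array 2 and 0.22 by the scanner software's log ratio. Of 15 hypoxia genes, 2 rose, none fell and 13 were not called, and 4 were up over the list alone. The called members were PCO1, a plant cysteine oxidase of oxygen sensing (1.29-fold), and the desaturase gene SAD6 (1.24-fold), and WIP4 was at 0.36 (adjusted p = 0.0503). The hypoxia list shifted up, with a median of 0.095 (adjusted p = 0.0367), with an adjusted p of 0.467 with an estimated correlation, and it lost its call without array 1, array 2 or array 3 (adjusted p = 0.117, 0.0787 and 0.1002, with 0.0218 to 0.467 over all camera settings tried).

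**Figure D3:**
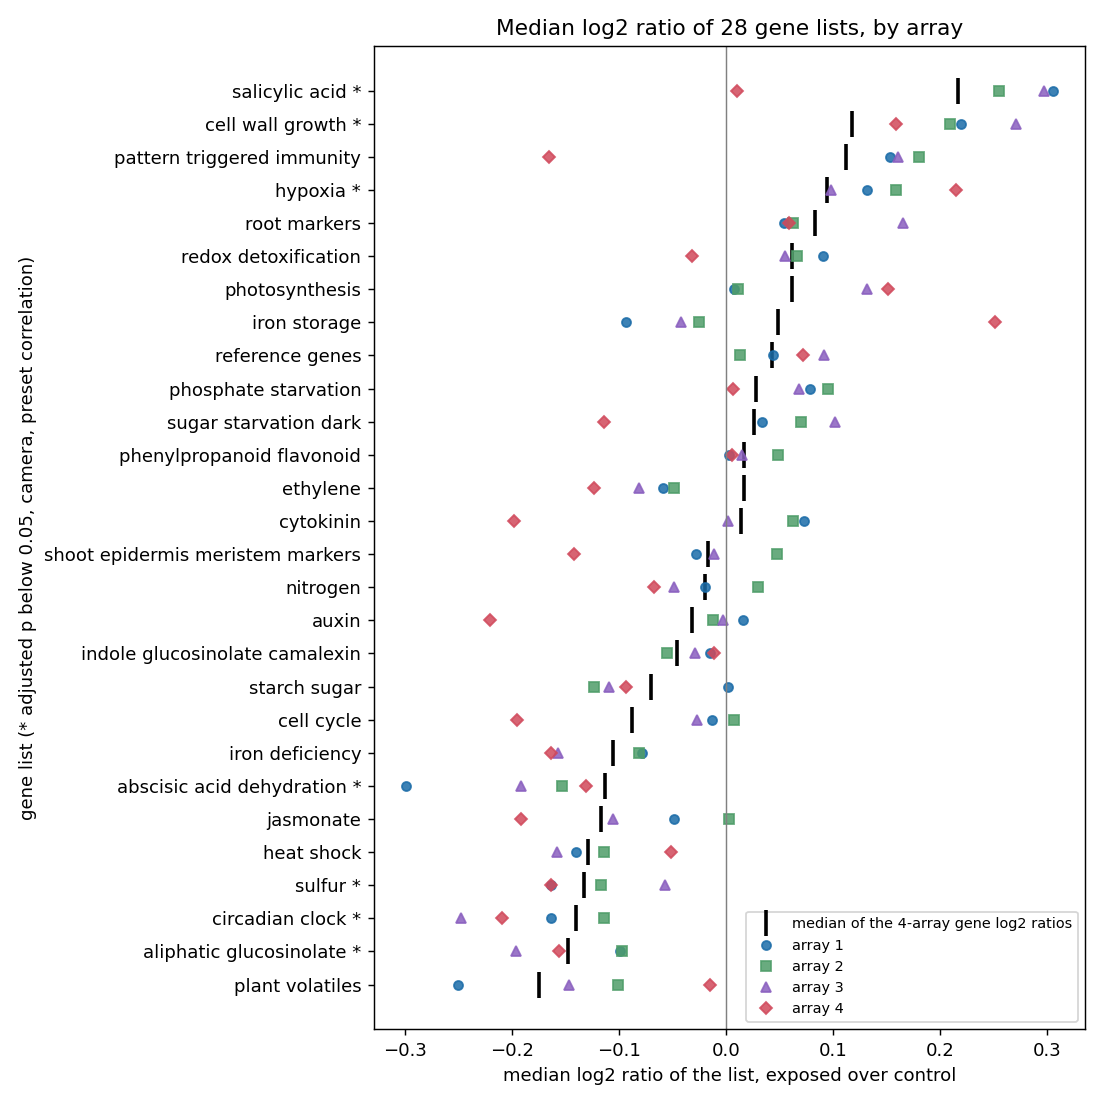
Median log2 ratio of exposed over control (horizontal axis) of each of 28 gene lists on each of the 4 arrays (symbols), with the median of the 4-array values as a black bar and an asterisk for lists called with the preset correlation. The salicylic acid list lies at 0.22 and the dehydration list at -0.11, and array 4 lies apart from the other arrays for pattern recognition, auxin and salicylic acid genes. The photosynthesis list changes sign with the scanner software's log ratio.

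Nuclear photosynthesis genes moved both ways, with 5 of 26 up and 1 down, and 8 up and 4 down over the list alone. LHCB1.3 (0.50), the Rubisco small subunit genes RBCS1A (0.49), RBCS2B (0.55) and RBCS3B (0.48), and PSBO1 (0.49) rose, and LHCB2.1 (-0.54) fell. These are families of near-identical copies whose probes can read each other's transcripts, and with the mean of its probes LHCB1.3 was at 0.12 (adjusted p = 0.227). The rises of LHCB1.3, RBCS1A and RBCS2B, and of PYK10, UBQ10 and AT1G07590, were read by very bright probes (log2 intensity 17.5 to 17.9). Chloroplast-encoded genes in that range lay between -0.10 and 0.40. Whether brightness affects these ratios was not tested. The list median was 0.062 (adjusted p = 0.168), and it changed sign with the scanner software's log ratio (-0.089) and with the mean of each gene's probes (-0.061), while median centring gave 0.34. Of 15 root marker genes, PYK10, an abundant root beta-glucosidase (0.61), and the root hair gene PRP3 (0.44) rose, CASP1 was at 0.27 (adjusted p = 0.0612), and over the list alone 5 were up and 2 down. The root list was not called by camera (median 0.083, adjusted p = 0.0581), with a median of 0.13 without array 3. Of 11 markers of shoot epidermis and meristems, AS1, a regulator of leaf polarity, fell (-0.49). Of the others, MUTE (0.24, or 0.13 without array 4) and YAB3 (0.23, or -0.017 with the mean of its probes) were not called. Over the list alone 1 was down. That list was not called (median -0.016, adjusted p = 0.869). Of 13 reference genes UBQ10 rose (0.43, but 0.056 with an adjusted p of 0.537 for the mean of its probes), while ACT8 (0.20), PP2AA3 (-0.20), ACT2 (0.14) and TIP41 (-0.022) were not called. Over the list alone 1 was up, and the list was not called (median 0.043, adjusted p = 0.208), with ACT2 at -0.044 and the list median at -0.013 under the scanner software's log ratio.

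The other lists were not called, with adjusted p between 0.141 and 0.899. Among nutrient genes, the iron uptake regulator FIT rose (0.42) and BHLH100 fell (-0.44), with BHLH39 at -0.31 uncalled (iron deficiency, 19 genes, median -0.11, at -0.044 without array 1 and -0.049 without array 4). Ferredoxin-dependent glutamate synthase GLU1 fell (-0.45), with NRT3.1 at 0.26 and UPM1 at -0.20 uncalled (nitrogen, 19 genes, median -0.020). None of 13 phosphate starvation genes was called, among them PHT1.4 (0.21), MGD2 (0.18) and PHT1.1 (0.22), nor of 4 ferritin genes, with FER4 at 0.071, FER2 at 0.098 and FER1 at -0.031. Among carbohydrate genes the starch dikinase gene SEX1 (-0.51) and the sugar exporter gene SWEET15 (-0.43) fell and the beta-amylase gene BAM5 rose (0.35, with a second probe at -0.17), with a list median of -0.070 over 10 genes. The dark-induced gene DIN2 fell (-0.74, with a second probe at -0.15). ASN1 at 0.26 and DIN10 at 0.18 were uncalled (sugar starvation, 6 genes, median 0.026, mean -0.071). Of 15 cell cycle genes the replication gene MCM2 fell (-0.44), with CYCB1.2 at -0.26 and CDKB2.1 at -0.21 uncalled. The list median was -0.088, and without array 4 it was -0.040 with CDKB2.1 at -0.13. No gene was called over all genes among 21 auxin genes (PIN2 -0.31, PIN3 -0.31 and -0.19 without array 4, GH3.3 0.21), 13 cytokinin genes (CKX3 0.25, IPT5 -0.14, CKX5 -0.19, the last 2 at -0.090 and -0.068 without array 4), 20 flavonoid genes (DFR -0.22, MYB12 0.18, LDOX -0.36 and -0.14 without array 4), 23 redox genes (CSD1 0.32, GSTF6 0.31, CAT1 -0.25) or 16 heat shock genes (HSP70-4 -0.28, MBF1C -0.32, ROF2 -0.28). The heat shock list was called without array 4 (median -0.15, adjusted p = 0.0174, with 0.0174 to 0.765 over all camera settings tried), and it too lost that call with an estimated correlation (adjusted p of at least 0.534). Adjusted over each list alone, counts of genes up and down were 1 and 6 for iron deficiency, 0 and 1 for nitrogen, 1 and 4 for starch and sugar, 1 and 1 for sugar starvation, 0 and 2 for the cell cycle, 2 and 1 for redox genes, 1 and 3 for heat shock genes, and 0 and 0 for the rest.

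Among 21 gene families found by words in the gene table, 5 shifted up. Xyloglucan endotransglucosylases, which remodel the cell wall, led them with a median of 0.18 over 31 genes (camera adjusted p = 8.9e-04). XTH33 (1.62-fold), XTH14 (1.39-fold), XTH18 and TCH4, another name of XTH22, were up and XTH10 down. XTH18 and XTH22 are also the called members of the cell wall list, so these results share genes. Expansins, the other members of that list, were not called as a family (26 genes, camera adjusted p = 0.512). WRKY transcription factors (67 genes, median 0.091, adjusted p = 0.0097) included WRKY50 and WRKY62 (1.24-fold), and UDP-glycosyltransferases (52 genes, median 0.090, adjusted p = 0.0097) included UGT71C2 (1.31-fold) and UGT87A2 (1.28-fold). Aquaporins (34 genes, median 0.080, adjusted p = 0.0168) included TIP2;3 (1.49-fold), PIP2;4 (1.32-fold), GAMMA-TIP (1.31-fold) and NLM1 (1.31-fold). Ethylene response factor and AP2 genes (37 genes, median 0.087, adjusted p = 0.0178) included RAV1 (1.41-fold) and RAP2.2 (1.34-fold), with a median of 0.11 to 0.13 on arrays 1 to 3 and -0.075 on array 4. WRKY factors and aquaporins were also below 0 on array 4 (-0.021 and -0.017), against 0.078 to 0.15 and 0.070 to 0.11 on arrays 1 to 3. With the wider word match tried at first, 158 genes, this family was not called (adjusted p = 0.249). The narrower match was chosen after that result was seen. With an estimated correlation 0 of 21 families were called, with adjusted p of 0.289 for xyloglucan endotransglucosylases and UDP-glycosyltransferases, 0.471 for WRKY factors and aquaporins and 0.51 for ethylene response factors. UDP-glycosyltransferases lost their call without array 4 (adjusted p = 0.0802), aquaporins without array 2 (0.0566), and ethylene response factors without array 1 (0.124) or array 2 (0.0566). The other 16 families were not called, with adjusted p between 0.0631 and 0.934. Without array 4 the heat shock family was called down (adjusted p = 0.0031, 18 genes down and 4 up) and receptor-like kinases up (0.0156), and without array 3 pectinesterases up (0.0444). Median centring called ribosomal proteins up (median 0.11, adjusted p = 0.0031, against 0.014 and 0.59 after loess). The scanner software's log ratio called pectinesterases up (0.0464), and scaled log ratios (0.0357) and the mean of each gene's probes (0.0427) called the heat shock family down. By median, the direction of the 5 called families was the same under each background correction and normalization tried.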

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

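Every test of an explanation in this part was chosen after the result was seen. Values are given where 1 array of the 4 lay far from the other 3, a mark that chance gives to about 1 in 20 groups of 4. It was met by 11 of 106 named genes, 4 of 28 lists, 4 of 21 families and 8 of 10 array measures, and array 4 was the one apart in 10, 3, 4 and 8 of these.

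Among genes, the camalexin genes PAD3 and CYP71A13 were at 0.21 and 0.40 on array 4 against -0.71 to -0.62 and -0.74 to -0.61 on the others. Falls were smaller on array 4 for DMP1 (-0.77 against -1.43 to -1.33), the cold- and dehydration-induced gene COR15A (-0.42 against -0.72 to -0.70) and the iron-deficiency regulator BHLH100 (-0.19 against -0.55 to -0.51). Array 4 was lower than the others for the defensin gene PDF1.2C (-0.77 against -0.36 to -0.35), the anthocyanin gene LDOX (-1.01 against -0.19 to -0.066), the auxin transporter gene PIN3 (-0.69 against -0.24 to -0.15) and GGCT2.1 (-0.59 against -0.35 to -0.32). The ferritin gene FER2 was at 0.68 on array 4 against -0.12 to -0.059, and the lipid synthase gene MGD2 at 0.35 on array 3 against 0.095 to 0.13.

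The median of the salicylic acid list was 0.010 on array 4 against 0.26 to 0.31, that of the pattern recognition list -0.17 against 0.15 to 0.18, and that of the auxin list -0.22 against -0.012 to 0.016. The root marker list was at 0.17 on array 3 against 0.055 to 0.063. Among families, the median on array 4 was -0.070 for NAC factors against 0.038 to 0.049, -0.075 for ethylene response factors against 0.11 to 0.13, 0.42 for late embryogenesis abundant proteins against -0.035 to -0.020, and 0.15 for xyloglucan endotransglucosylases against 0.166 to 0.170.

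Array 4 had a median Cy5 signal of 1286 units against 336 to 373, and 97.2% and 99.6% of its gene spots were well above background in Cy3 and Cy5, against 75.1% to 75.4% and 77.7% to 78.9%. Its negative controls read 58.1 units in Cy3 against 31.0 to 33.9 and 83.2 in Cy5 against 20.4 to 21.7. The slope of spike-in log ratios was 0.614 against 0.869 to 0.871, their correlation 0.824 against 0.985 to 0.987, and 142 spots were outliers against 13 to 19. Raised signal at dim spots is a candidate explanation, since the correlation of array 4 with the mean of the others was higher by 0.585 (0.551 to 0.62) in the brightest of 5 bins of genes than in the dimmest. Exchanged tubes or dyes would give a negative correlation, and it was 0.275 (0.262 to 0.288) over all genes. The ranges in parentheses here come from resampling genes, which are not independent, and hold nothing of the spread between arrays. Whether the plants of array 4 responded differently stays open. Among the brightest genes array 4 resembled the others, at 0.747 (0.73 to 0.763) where the lowest of the other arrays was at 0.714. Array 4 was set against the mean of arrays 1 to 3, and each other array against a mean of only 2, which favours array 4. A dye preference shared by all arrays would also raise these correlations.

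Outside the comparison of genes, 59 of 3010 tested probes without a locus identifier were called in a fit of 34116 probes, 39 higher and 20 lower, with log2 ratios from -0.74 to 1.02.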

How the results depend on the processing

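Counting arrays 1 to 3 as 1 sample, the narrower AP2 match and families without each array were chosen after the results were seen. With 1 array left out the count ran from 0 without array 1, 2 or 3 to 7067 without array 4, and that at 2-fold from 0 to 16. Over all settings the highest counts were 8245 and 114. Salicylic acid, cell wall, dehydration and sulfur lists stayed called in each fit without 1 array, and called families numbered 3 to 6 there. The deposited matrix gave no value for arrays 2 to 4, since its columns hold no ratio of the 2 signals. Signal over background limits dim genes on arrays 1 to 3, where about 75.1% to 78.9% of gene spots were well above background. Agreement on dim genes was nevertheless lowest for array 4. In the dimmest bin of genes by brightness, array 4 correlated with the mean of arrays 1 to 3 at 0.162. Each of arrays 1 to 3 correlated there with the mean of the rest of arrays 1 to 3 at 0.671 to 0.694. The cause was not tested for any change below.

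With 1 array left out, list medians that changed side or sign ranged as follows: ethylene -0.046 to -0.019, pattern recognition 0.090 to 0.17, aliphatic glucosinolate -0.16 to -0.15, plant volatiles -0.20 to -0.14, cytokinin -0.013 to 0.041, photosynthesis -0.0021 to 0.095, sugar starvation -0.0042 to 0.073, hypoxia 0.064 to 0.11, heat shock -0.15 to -0.085, ferritins -0.049 to 0.086, phosphate -0.047 to 0.053, clock -0.15 to -0.093 and shoot markers -0.053 to 0.035. Others that moved by over 1.5 times were jasmonate -0.14 to -0.031, flavonoid 0.0070 to 0.027, auxin -0.056 to -0.024, cell wall 0.12 to 0.19, dehydration -0.17 to -0.12, nitrogen -0.027 to -0.0069, iron deficiency -0.090 to -0.044, cell cycle -0.12 to -0.040 and root markers 0.081 to 0.13. Genes that changed sign were FER4 (-0.031 to 0.13), FER2 (-0.097 to 0.17), FER1 (-0.067 to 0.015) and TIP41 (-0.044 to 0.010).

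Arrays 1 to 3 counted as 1 sample gave 0 genes and 0 at 2-fold (1317 at an unadjusted p below 0.05 in limma). The calls were lost for aliphatic glucosinolate (-0.16), hypoxia (0.14), sulfur (-0.16) and clock lists (-0.17), and the sign turned for ethylene (-0.055), cytokinin (-0.040), sugar starvation (-0.020) and FER1 (0.0057). With an estimated correlation 0 families and 0 lists were called, so salicylic acid (0.22), aliphatic glucosinolate (-0.15), cell wall (0.12), dehydration (-0.11), hypoxia (0.095), sulfur (-0.13) and clock (-0.14) lost their calls. With fry, which does not compare a list with other genes, salicylic acid (0.22) and aliphatic glucosinolate (-0.15) lost theirs, and indole glucosinolate (-0.045), plant volatiles (-0.17), root markers (0.083) and reference genes (0.043) gained one.

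Without the pairing of channels within an array (no replicate block) 91 genes were called and 8 at 2-fold, photosynthesis (0.062), heat shock (-0.13) and root markers (0.083) gained a call and hypoxia (0.095) lost it. Slide as a random block gave plant volatiles (-0.17) and root markers (0.083) a call. Trend and robust eBayes called 2196 genes, added photosynthesis (0.062) and root markers (0.083) and lost hypoxia (0.095). Array weights (3.02, 2.36, 0.902 and 0.156 for arrays 1 to 4) called 8245, added pattern recognition (0.18), plant volatiles (-0.19), heat shock (-0.14) and root markers (0.039), lost aliphatic glucosinolate (-0.15), and turned ethylene (-0.032), photosynthesis (-0.0024), ferritins (-0.058), shoot markers (0.023), FER4 (-0.0042), FER2 (-0.090) and TIP41 (0.019).

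Median centring called 216 genes, added pattern recognition (0.16), redox (0.17), plant volatiles (-0.098), photosynthesis (0.34), root markers (0.088) and reference genes (0.26), lost aliphatic glucosinolate (-0.077), and turned indole glucosinolate (0.071), nitrogen (0.076), shoot markers (0.037) and GGP1 (0.041). Scaled log ratios called 3812, added pattern recognition (0.14) and plant volatiles (-0.19), and turned ethylene (-0.054), shoot markers (0.010) and FER2 (-0.0013). The scanner software's log ratio gave 114 genes at 2-fold, 104 up and 10 down, added jasmonate (-0.11), lost aliphatic glucosinolate (-0.13), and turned ethylene (-0.041), photosynthesis (-0.089), phosphate (-0.014), reference genes (-0.013), MGD2 (-0.014) and ACT2 (-0.044). Plain background subtraction gave 42 at 2-fold, 33 up and 9 down, and turned ethylene (-0.0067). The mean of a gene's probes added jasmonate (-0.13) and pattern recognition (0.12), lost hypoxia (0.095), and turned ethylene (-0.0049), auxin (0.0048), photosynthesis (-0.061), GGP1 (0.034), FER1 (0.012) and YAB3 (-0.017). No filter called 292 genes and lost hypoxia (0.078), and the strict filter added pattern recognition (0.11), plant volatiles (-0.19) and root markers (0.083). The wider AP2 match, run first, left 4 families called. Medians that moved by over 1.5 times without a change of call included jasmonate with median centring (-0.051) and array weights (-0.025), pattern recognition (0.042) and iron deficiency (-0.035) with arrays 1 to 3 as 1 sample, plant volatiles without a filter (-0.027), redox by the scanner software's log ratio (0.017) and sulfur with median centring (-0.050).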

Other observations

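The tests of curvature after loess, of dye bias of whole transcripts and of turned signs were set before their results were seen, and the other tests in this part after.

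Most transcripts encoded in the chloroplast genome read lower in exposed plants. Of 66 tested, 36 were called lower and 0 higher, 59 had a log2 ratio below 0, and their median was -0.39, at -0.36, -0.36, -0.43 and -0.38 on arrays 1 to 4. The largest differences were in ATCG01130 (-0.74) and ATCG01090 (-0.72), loci without a symbol in the gene table that were chosen after their values were seen. The genes above 0 were among the brightest of the set (log2 intensity 16.8 to 17.7), led by ATCG00020 (0.40) and ATCG00300 (0.39), both uncalled. ATCG00480, at 17.1, was at -0.41, with a second, dimmer probe at -0.84. Second probes of ATCG00440, ATCG00040 and ATCG00020 also read lower than the brightest probe (-0.58 against -0.015, -0.18 against -0.018 and 0.21 against 0.40). Those of ATCG01130, ATCG00860 and ATCG00350 read higher (-0.60 against -0.74, -0.29 against -0.48 and -0.16 against -0.47). As a set the chloroplast-encoded genes were lower than other genes (camera p = 5.7e-21), with p = 0.0035 with an estimated correlation, a set chosen after the data were seen. Without array 4 there were 49 lower and 5 higher, and with median centring in place of loess the median was -0.23, with 4 higher and 3 lower and a median SD between arrays of 0.292 against 0.111 after loess. Of 62 transcripts encoded in the mitochondrial genome 4 were called lower and 1 higher, 41 had a log2 ratio below 0, and as a set they too were lower than other genes (camera p = 0.0086), with p = 0.0446 with an estimated correlation. Without array 4 there were 16 lower and 3 higher.

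Chloroplast-encoded transcripts are among the brightest spots, with a median log2 intensity of 14.7 against 9.91 for other genes, and the median of nuclear genes of matched brightness, 0.027, decides nothing after loess, which sets it near 0. Without loess matched nuclear genes had a median of 0.17 (0.076 to 0.26 over 1000 random sets) where chloroplast-encoded genes had -0.23. On arrays 1 to 4 the chloroplast medians were -0.049, -0.037, -0.20 and -0.63, against 0.27, 0.38, 0.28 and -0.22 for matched nuclear genes. Array 4 thus weighed most in the value of -0.23. That the chloroplast-encoded genes were the lower on each array argues against a curve of log ratio with brightness as the whole cause. A link with brightness within the chloroplast set was not tested. A lower share of green tissue would lower the nuclear photosynthesis list too, whose median was 0.062 (-0.032 to 0.18, from resampling its genes). That median changed sign with the scanner software's log ratio. The root marker list had a median of 0.083 (adjusted p = 0.0581 by camera and 4.5e-04 by fry), so a lower green share is not excluded. By fry, which does not compare a list with other genes, the reference genes were called too (median 0.043, adjusted p = 0.0131). A lower yield of RNA with short poly(A) tails was taken to lower mitochondrial transcripts as much. Their median was -0.055 (-0.10 to -0.022, from resampling genes), and as a set they too were lower than other genes. Equal loss in both organelles was assumed and not tested, so this comparison cannot decide. A dye preference of the chloroplast-encoded transcripts stays open, since no array had swapped dyes. A response to the volatiles may be the cause only as a hypothesis.

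The shared log ratios of the arrays were weighed in the same way. The log ratios of 2 probes of a gene correlated at 0.385 (0.358 to 0.411) across 6495 genes, against 0.00844 for probes of random genes, which argues against a dye preference of single probes as the whole cause. A dye preference of whole transcripts cannot be told apart from an effect of exposure, because 0 arrays had swapped dyes. Whether arrays 1 to 3 are repeated hybridisations of the same pair of RNAs stays open. Their differences, read by 2 probes of a gene, correlated at 0.0131 at most (-0.0098 to 0.039), but pairs with array 4 were also low, at 0.0301 to 0.0378, so that this test could not separate repeats from other pairs. The ranges in parentheses come from resampling genes of the same arrays, not from the spread between arrays.

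Turning the sign of some arrays gives 8 patterns, which are too few for a share under 0.05. For each count 1 of the 8, the real signs, gave as many, with 772 genes against at most 0 in limma for the others (24 to 2194 genes at an unadjusted p below 0.05, against 5629), 14 against 0 genes at 2-fold, and 7 against 5 lists, the 5 coming from the pattern with array 4 turned.

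Log ratios of neighbouring genes correlated at 0.0508 across 15370 adjacent pairs, against 3.7e-04 with the second gene drawn at random.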
